A study of Mus musculus with 6 samples.

How the data were processed

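Total RNA from left ventricular tissue of 6 male mice was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 array per mouse, per the labels. The 3 sickle mice were homozygous for engineered human globin alleles that give sickle haemoglobin, and the 3 control mice carried a matching set with a non-sickling human beta-globin, both on a mixed strain background. The groups and replicate numbers were taken from the sample titles, and the labels list the arrays as separate mice of a group.

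The values were deposited by the authors on the log2 scale after RMA, a procedure that corrects the background, normalises the arrays to 1 distribution by quantiles and summarises the probes of each transcript cluster, per the submitters' processing notes, which name RMA without a version. The settings of that step, the scan dates and any batch are not given in the sources used here. The log2 scale was read from the values themselves. The deposited table held 25293 rows, and the array medians lay between 5.500 and 5.543. Array platform annotation gave exactly 1 gene symbol to 22030 rows, several to 685 and none to 2578. Of the 22030 rows, 21930 had a gene number found in the RefSeq gene table for assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. No coordinates are printed, since the build behind the array table is not given in the sources used here.

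Rows with 1 symbol entered the tests. For 465 genes with more than 1 row, the row with the highest mean over the 6 arrays stood for the gene, which left 21506 genes. Dcaf12 and Emb were the 2 called genes with more than 1 row, and in both the dimmer row had a smaller log2 difference (0.22 for Dcaf12 and -0.02 for Emb). No filter on dim genes was set. Limma 3.58.1 in R 4.3.3 was run with lmFit and eBayes on the log2 values with group as the only term, with 4 residual and 3.61 prior degrees of freedom, two-sided, and Benjamini-Hochberg adjustment over all 21506 genes at 0.05. Differences are sickle minus control, and standard errors are the moderated ones. A looser count, genes at an unadjusted p under 0.01 and at least 1.5-fold, does not control false calls. Arrays give no read depth, so the number of arrays limits the precision.

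A set of 29 gene lists covering heart function, metabolism, stress, inflammation and the other cell types that ventricular tissue holds was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Called genes were also tested for list membership with Fisher's exact test. The IL-18 genes were further tested with an exact two-sided permutation test, for which 3 against 3 arrays allow no p below 0.1. Genes among the 100 named or protein-coding neighbours on either side of the beta-globin locus were compared with all others by Fisher's exact test, since the engineered alleles lie there.

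The comparison, lists, alternatives, rule for naming genes and tests described so far were fixed before the data were examined, except the test of called genes for list membership. That test and the tests of explanations in the closing section were added afterwards. The rule takes the 12 genes higher and the 12 lower in sickle with the largest differences among called genes without overlap between groups, filled where too few were called by the smallest p among genes without overlap at the looser limit, and passes over symbols of predicted or unnamed genes, which left out 1 called gene. It adds, from each list, members past the adjustment or otherwise those with the smallest p, a fixed set of genes of interest in heart and sickle disease, and sex-linked genes. Of these, Alas2, Ddx3y and the adult mouse globin genes were not among the genes tested.

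The procedure was tested on simulated data for sickle against control with 3 arrays against 3 and 21506 genes. Of the genes changed by 1.5-fold, 21 of 67 (31.3%) were called, of those changed by 2-fold 51 of 67 (76.1%), and of those changed by 4-fold 63 of 66 (95.5%). Among 137 calls, 2 were of unchanged genes, and 20 simulated sets with no change gave 0 calls. Camera recovered 40 of 40 lists whose genes were all shifted by 0.5 on the log2 scale, and called 5 others over 20 draws. The simulated genes were drawn without correlation, and smaller list shifts were not simulated. The alternatives tried were another variance model, a filter on dim genes, a second quantile normalisation, median centring, array weights, the replicate number as a block, leaving out each array in turn, the mean over a gene's rows, all rows, a test without shared variance, and other list tests. Figures were drawn with matplotlib 3.10.9.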

Results

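Gene expression was measured in left ventricle of 3 control and 3 sickle male mice on 6 arrays. The arrays were of similar brightness, with upper quartiles from 7.27 to 7.37 on the log2 scale. Xist, the RNA of the inactive X chromosome, was dim in both groups (3.91 ± 0.17 in control and 3.75 ± 0.34 in sickle, SD, n = 3), while the Y-linked Eif2s3y (8.75 ± 0.06 and 8.68 ± 0.30), Uty (7.93 and 7.89) and Kdm5d (6.89 and 6.96) were bright in both groups, all labelled male. One sickle array, replicate 3, stood apart from the other arrays. The first principal component (43.9% of the variance) had a score of 43.3 for that array and scores from -15.1 to -2.31 for the others. In that array 340 genes were over 2-fold above the mean of its group mates, against 13 to 25 genes in each of the other arrays.

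The comparison asked how the ventricle of mice with sickle haemoglobin differs from that of mice with a non-sickling human haemoglobin. Transcripts of red cells rose in the sickle ventricle. Slc4a1, the band 3 anion exchanger of the red-cell membrane, rose 9.93-fold, from 6.64 ± 0.31 in control to 9.95 ± 0.63 in sickle (log2, SD, n = 3; difference 3.31 ± 0.30, SE; limma adjusted p = 0.0109). Apol11b, of the apolipoprotein L family, rose 10.5-fold (difference 3.40 ± 0.26, adjusted p = 0.00708), and Car2, a carbonic anhydrase abundant in red cells, rose 5.30-fold (2.41 ± 0.24, adjusted p = 0.0162). In the other direction, Timp4, an inhibitor of matrix metalloproteinases made in heart muscle, was 2.97-fold lower (difference -1.57 ± 0.13, adjusted p = 0.00870), and Scn4b, the beta-4 subunit of the voltage-gated sodium channel, was 1.94-fold lower (-0.95 ± 0.11, adjusted p = 0.0251).

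In all, 39 of 21506 genes passed an adjusted p of 0.05, 36 of them higher and 3 lower in sickle. The 3 sickle values lay on one side of the 3 control values for all 39 genes. Over all genes, 3434 (16.0%) had no overlap between the groups, where chance gives 10%. An unadjusted p under 0.05 was reached by 1868 genes (8.69%), and 178 genes had an unadjusted p under 0.01 and at least a 1.5-fold difference, 118 higher and 60 lower. The count of 39 depended on single arrays: it was 13, 5 and 4 without control replicates 1, 2 and 3, and 21 without sickle replicate 2 or sickle replicate 3. Tent5c, Rsad2, Cd24a and Prxl2a were the 4 genes called with any 1 array left out. Car4, Ncoa4, Ccndbp1, Tspan33 and Cd79a were called in none of those 6 fits (Prxl2a, Ncoa4, Ccndbp1 and Tspan33 were chosen after their values were seen). Without overlap between the groups, no called gene could turn its direction in these fits.

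Among the other genes with the largest rises, Ctse, the aspartic protease cathepsin E, differed by 2.51 ± 0.23, and Tent5c, a poly(A) polymerase, by 2.42 ± 0.14. Cd24a, a surface antigen of immature blood cells, differed by 2.33 ± 0.15, and Hbq1a, a theta-globin gene, by 2.28 ± 0.21. Epb42 (protein 4.2 of the red-cell membrane skeleton, 2.27 ± 0.29) and Trim10 (a regulator of red-cell maturation, 2.19 ± 0.25) followed. Rsad2, an interferon-inducible antiviral enzyme, rose by 2.10 ± 0.13 with an adjusted p of 0.00274. Slfn14, of the Schlafen family, rose by 2.08 ± 0.22, and the pseudogene Cyp4b1-ps2 by 2.70 ± 0.34. The adjusted p of these genes lay between 0.00274 and 0.0431.

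Of the lower genes, Car4, a membrane-bound carbonic anhydrase, had a difference of -0.90 ± 0.10 (adjusted p = 0.0287). The next 9 lower genes did not pass the adjustment, with adjusted p from 0.0528 to 0.155. They included Acot1 (-1.52 ± 0.21) and Acot2 (-0.83 ± 0.12), both acyl-CoA thioesterases, and Aqp7, a glycerol channel (-0.66 ± 0.10). Cacna1h, a T-type calcium channel, had -0.76 ± 0.13, and Cdkn1c, a cyclin-dependent kinase inhibitor, had -0.69 ± 0.11. The natural killer cell receptor gene Klra9 had -1.44 ± 0.20, Sult2a5 -0.86 ± 0.13, Asb5 -0.60 ± 0.09 and Cyp2a22 -0.61 ± 0.10.

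**Figure D1:**
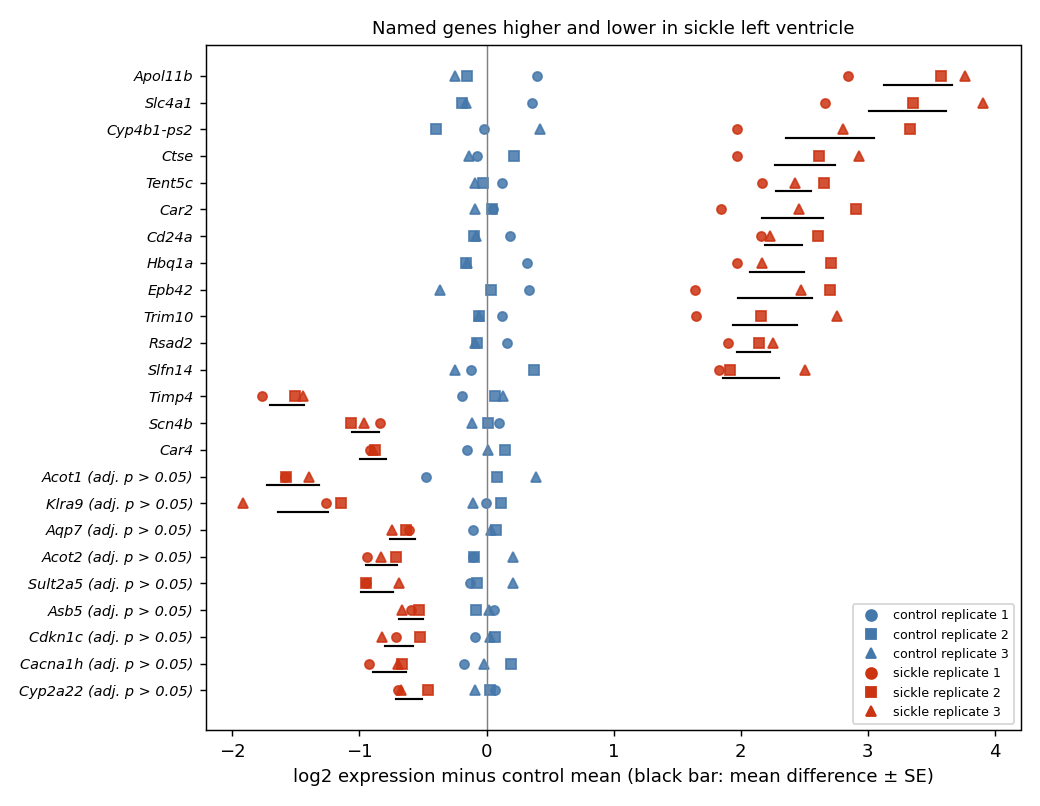
Log2 expression of each array minus the control mean (horizontal axis) for the named genes (vertical axis), with blue points for 3 control and red points for 3 sickle arrays and a black bar for the mean difference ± SE. Slc4a1 differs by 3.31 and Timp4 by -1.57, and the 9 genes with a marked name did not pass the adjustment.

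Of 18 measured reticulocyte and erythroid markers, 17 were higher in sickle, with a median difference of 1.55. Of these, 9 rose after adjustment over all genes, and 13 when adjusted over the list alone. Besides Slc4a1, Epb42 and Trim10, these included Bpgm, which makes 2,3-bisphosphoglycerate (1.71 ± 0.12, adjusted p = 0.00491), Isg20, an exonuclease (2.00 ± 0.18), Ube2l6, a ubiquitin-like protein conjugating enzyme (1.78 ± 0.15), Mkrn1, a ubiquitin ligase (1.77 ± 0.19), Slc25a37, the mitochondrial iron importer mitoferrin (1.88 ± 0.22), and Rhag, the Rh-associated glycoprotein (1.57 ± 0.21). Fech, which inserts iron into protoporphyrin, had 1.05 ± 0.15 and passed over the list alone. The median of the list relative to control was 1.09, 1.66 and 1.58 in sickle replicates 1, 2 and 3, and between -0.06 and 0.03 in the control arrays. Camera gave an adjusted p of 2.31e-26 at the preset correlation, against an adjusted p = 0.165 with an estimated correlation; fry gave an adjusted p of 0.0135. The list held 9 of the 36 genes called higher, where 27 others lay among 21488 genes (two-sided Fisher's exact test, adjusted p = 4.85e-20 over 29 lists; genes are not independent replicates).

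Across the 29 lists, camera at the preset correlation called 14, of which 12 were higher and 2 lower in sickle. With an estimated correlation 0 lists passed (3 had an unadjusted p under 0.05), and fry called 1, the red-cell list. Without sickle replicate 3, camera called 7 lists: red-cell, lymphocyte, cell cycle, oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, and glucocorticoid response genes (the red-cell list at an adjusted p of 9.65e-23, and adjusted p = 0.212 with an estimated correlation).

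Lymphocyte markers were higher, with 13 of 16 above control and a median of 0.26 (camera adjusted p = 6.86e-06, and adjusted p = 0.191 with an estimated correlation). The B-cell receptor subunit gene Cd79a rose by 1.12 ± 0.15 (adjusted p = 0.0484), and with Ms4a1 (CD20, 0.69 ± 0.12) and Cd79b (0.65 ± 0.16) it made 3 genes adjusted over the list alone, against 1 over all genes. Neutrophil markers had a median of 0.11 and did not pass (camera adjusted p = 0.212), with Ngp at 0.25, Hdc at 0.28 and Camp at -0.30. Cell cycle genes were higher, 18 of 19, with a median of 0.39 (camera adjusted p = 7.36e-09, and adjusted p = 0.517 with an estimated correlation). Relative to control, that list's median was 0.12, 0.46 and 0.53 in sickle replicates 1, 2 and 3. It lay between -0.08 and 0.10 in the control arrays, so sickle replicate 1 was close to the highest of these. Nusap1, a spindle protein, was the 1 member past the test adjusted over the list alone (0.69 ± 0.14), and 0 members passed over all genes. Both the lymphocyte and the cell cycle list were also called without sickle replicate 3 (adjusted p = 1.16e-05 and 3.39e-06, against an adjusted p = 0.212 and 0.798 with an estimated correlation).

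Genes of mitochondrial fuel use were lower. All 30 measured oxidative phosphorylation genes were below control, by a median of -0.18 (camera adjusted p = 1.18e-07, and adjusted p = 0.628 with an estimated correlation), though 0 passed singly, over the list alone or over all genes. Cox7a1, a heart and muscle subunit of cytochrome oxidase, had -0.32 ± 0.10, Sdhc -0.34 ± 0.12 and Cox5b -0.25 ± 0.09. Of 21 fatty acid oxidation genes, 20 were lower, with a median of -0.21 (camera adjusted p = 3.43e-08, and adjusted p = 0.445 with an estimated correlation). Adjusted over the list alone, 4 of them fell, and 0 over all genes: Acot1, Acot2, Pdk4, a kinase that shuts off pyruvate oxidation (-1.54 ± 0.33), and Slc25a20, the mitochondrial carnitine carrier (-0.49 ± 0.11). The medians were deeper in sickle replicate 3 (-0.36 and -0.42) than in replicates 1 (-0.05 and -0.16) and 2 (-0.10 and -0.14), and both lists were called without replicate 3 (adjusted p = 0.00269 and 3.39e-06, against an adjusted p = 0.798 and 0.212 with an estimated correlation). Sarcomere genes, the contractile markers of cardiomyocytes, had a median of -0.05 (camera adjusted p = 0.229), with Tcap at -0.22, Ldb3 at -0.26 and Myoz2 at -0.17, none past the adjustment. Relative to control, their median was 0.03, -0.01 and -0.14 in sickle replicates 1, 2 and 3, and the difference was 0.04 without replicate 3. Glycolysis and hypoxia genes were higher, 14 of 20, by a median of 0.11 (camera adjusted p = 0.0125, and adjusted p = 0.517 with an estimated correlation; without replicate 3, adjusted p = 0.0113, and adjusted p = 0.798 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, had 0.65 ± 0.17, Slc2a1 0.39 ± 0.14 and Adm 0.31 ± 0.11, with 0 members past either adjustment.

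Matrix, fibroblast and macrophage genes were called higher as lists, and the lists lost their calls without 1 array, sickle replicate 3. Extracellular matrix genes had a median of 0.66 (21 of 24 higher, camera adjusted p = 1.68e-05, and adjusted p = 0.628 with an estimated correlation), but relative to control the median was 0.01, 0.04 and 1.85 in sickle replicates 1, 2 and 3, and 0.06 over the first 2 of these (adjusted p = 0.533). Fibroblast markers had medians of 0.01, 0.08 and 0.93, and macrophage and monocyte markers 0.03, 0.07 and 1.24; both were called over 6 arrays (adjusted p = 0.00120 and 0.000885, each with an adjusted p = 0.628 with an estimated correlation) and not without replicate 3 (adjusted p = 0.337 and 0.477). No member of these 3 lists passed alone or within its list over 6 arrays. Postn (periostin, 1.85 ± 0.74), Col14a1 (1.79 ± 0.55), Tgfb1 (0.41 ± 0.12), Lum (0.79 ± 0.28), Mfap4 (0.94 ± 0.39), Gsn (-0.18 ± 0.09), Csf1r (0.63 ± 0.25), Lyz2 (0.71 ± 0.30) and Adgre1 (0.75 ± 0.38) had the smallest p. Some of these members were above every control array in all 3 sickle arrays: Col14a1 had 6.91, 6.71 and 9.02, against at most 5.92 in control. Without replicate 3 the difference was 1.06 for Col14a1 (adjusted p = 0.134), 0.87 for Postn (adjusted p = 0.369) and 0.42 for Lum (adjusted p = 0.303).

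The other 5 lists called at the preset correlation were immediate early genes (median 0.20, adjusted p = 0.00552), NF-kB cytokines and adhesion genes (0.09, adjusted p = 0.00867), coagulation and complement genes (0.26, adjusted p = 0.00958), smooth muscle and pericyte markers (0.14, adjusted p = 0.0207) and endothelial markers (0.10, adjusted p = 0.0377). Each had an adjusted p = 0.628 with an estimated correlation, and none was called without sickle replicate 3 (adjusted p from 0.170 to 0.750). Their medians without that array were, in the same order, 0.04, 0.06, -0.01, 0.05 and 0.05. Within them, Vwf, the endothelial clotting factor, rose adjusted over the list alone (1.13 ± 0.22; 1 member, and 0 over all genes), as did the chemokine Ccl5 (0.71 ± 0.11; 1 member, and 0 over all genes). Egr1 (0.68 ± 0.26), Fosb (0.46 ± 0.15), Ier2 (0.45 ± 0.15), Acta2 (0.37 ± 0.12), Myh11 (0.28 ± 0.09) and Vtn (-0.45 ± 0.14) did not pass.

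**Figure D2:**
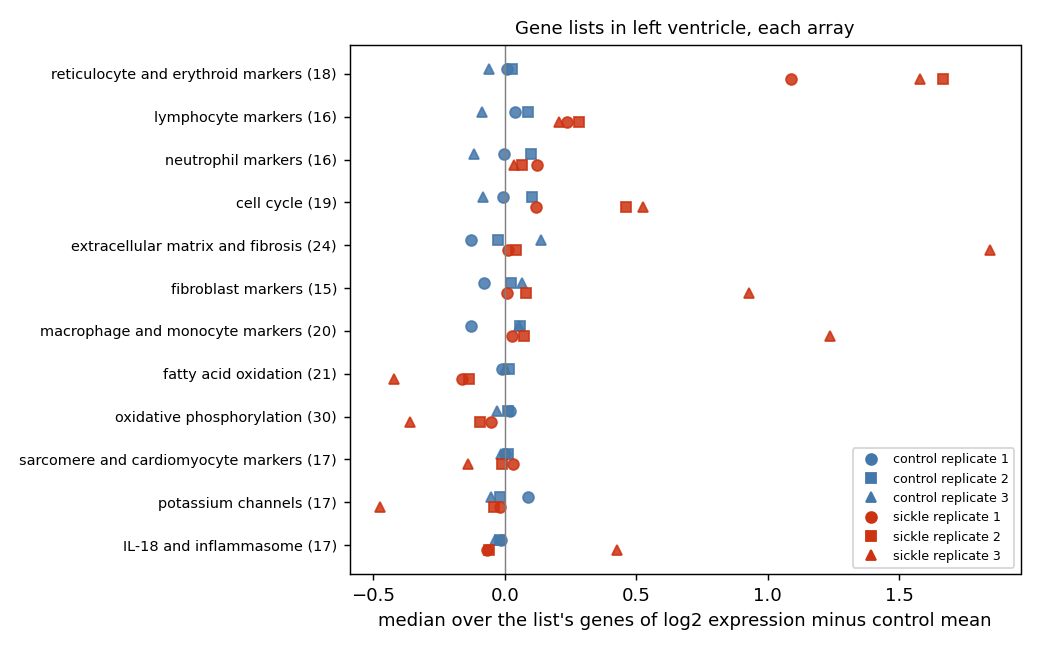
Median over each list's measured genes (number in parentheses) of log2 expression minus the control mean (horizontal axis), 1 point per array, blue for control and red for sickle. The red-cell list lies at 1.09 to 1.66 in all 3 sickle arrays, while the matrix list lies at 1.85 in sickle replicate 3 and at 0.01 and 0.04 in the other sickle arrays.

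The study's stated interest was IL-18, a cytokine matured by caspase-1. Il18 itself was dim, at the 18.0 percentile of all genes, and did not differ beyond the spread between arrays (3.75 ± 0.07 in control and 3.82 ± 0.33 in sickle, SD, n = 3; difference 0.07, 95% interval -0.31 to 0.45; exact two-sided permutation p = 1). Il18r1, a receptor subunit, differed by -0.05 (95% interval -0.59 to 0.50, exact permutation p = 0.8), and Il18rap, its partner, by 0.24 (-0.28 to 0.76, exact permutation p = 0.5). The decoy receptor gene Il18bp differed by -0.13 (-0.41 to 0.15, exact permutation p = 0.4) and Casp1 by 0.21 (-0.19 to 0.62, exact permutation p = 0.6). The exact p-values adjusted over these 5 genes were all 1, and 3 against 3 arrays allow none below 0.1; the limma adjusted p lay between 0.741 and 0.964. Without sickle replicate 3 the differences of Il18, Il18rap and Casp1 were -0.12, 0.06 and 0.01. Changes within these intervals could not be told from no change with 3 arrays per group. Of 17 IL-18 and inflammasome genes, 0 passed over the list alone or over all genes, with a median of 0.07 (camera adjusted p = 0.212); the list's median was 0.43 in sickle replicate 3 and -0.07 and -0.06 in replicates 1 and 2. Aim2 (0.43 ± 0.22), Il1r1 (0.40 ± 0.22) and Traf6 (-0.12 ± 0.10) had the smallest p; without sickle replicate 3, Aim2 differed by 0.17 and Il1r1 by 0.14.

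**Figure D3:**
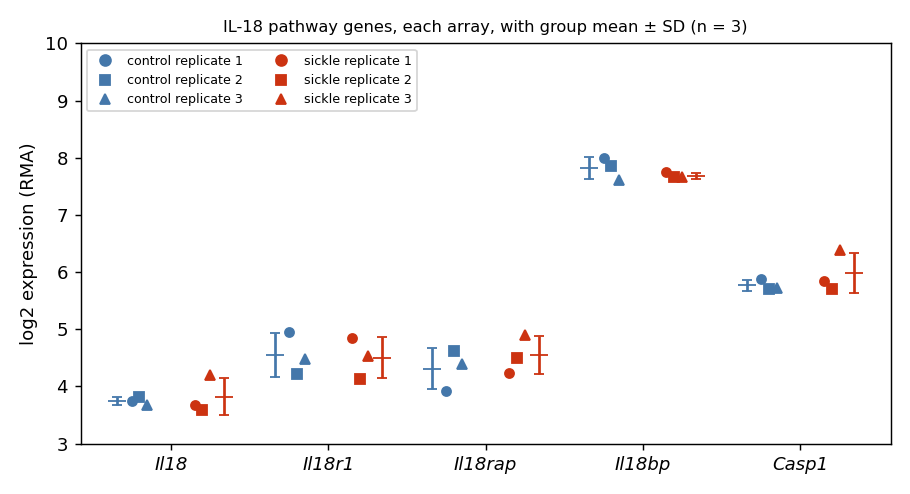
Log2 expression after RMA (vertical axis) of 5 IL-18 pathway genes (horizontal axis) in 3 control (blue) and 3 sickle (red) arrays, with bars for the group mean ± SD. For Il18 the means are 3.75 and 3.82.

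Among ion channel genes, Scn4b fell after adjustment over all genes, and Scn4b and Cacna1h were the 2 of 16 sodium channel, calcium channel and gap junction genes past the test adjusted over the list alone; the list's median was 0.01, its mean -0.11 and its camera adjusted p 0.238. Scn4b was called with 1 of the 6 arrays left out and lost its call in the other 5 such fits (adjusted p up to 0.196). Gja1, the main ventricular gap junction gene, differed by 0.01 ± 0.11. Potassium channel genes had a median of -0.17 (12 of 17 lower, camera adjusted p = 0.121), with 0 past either adjustment. Kcnd2 and Kcnip2, of the transient outward current, differed by -0.33 ± 0.21 and 0.46 ± 0.17, Dpp6 by 0.53 ± 0.15, Kcnj5 by -0.50 ± 0.17 and Kcnj3 by -0.48 ± 0.18. The median of the potassium channel list was -0.47 in sickle replicate 3, -0.02 in replicate 1 and -0.04 in replicate 2. Of 18 calcium handling genes, Atp2b4, a plasma membrane calcium pump, was the 1 that rose adjusted over the list alone (0.57 ± 0.11; 0 over all genes; list median -0.06, camera adjusted p = 0.899).

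Markers of cardiac stress and hypertrophy did not pass. Nppa, the atrial natriuretic peptide gene, was higher in 3 of 3 sickle arrays (12.70 ± 0.06 in control and 13.27 ± 0.35 in sickle; difference 0.57 ± 0.17, adjusted p = 0.451; without sickle replicate 3, 0.37 and adjusted p = 0.396). Nppb differed by 0.04 ± 0.11, the alpha myosin gene Myh6 by -0.02 ± 0.09 and the fetal myosin gene Myh7 by 0.92 ± 0.54 (adjusted p = 0.653; without sickle replicate 3 the difference was 0.33 and the adjusted p 0.833). The 19 fetal program genes had a median of 0.01 (camera adjusted p = 0.984), with Hand2 at -0.38 ± 0.12 and Xirp1 at -0.31 ± 0.10, and the atrial and skeletal muscle list had a median of 0.03, a mean of -0.15 and a camera adjusted p of 0.899, with Bmp10 at -0.35 ± 0.15 and Myh2 at -0.43 ± 0.23. Control replicate 3 stood apart in both lists: the atrial genes Sln and Myl7 (chosen after their values were seen) had 8.08 and 7.75 there, against 3.10 to 3.36 and 4.31 to 4.78 in the other 5 arrays.

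Heme, iron and antioxidant genes had a median of 0.00 and a mean of 0.05 (camera adjusted p = 0.350). The mean was pulled down by Hamp (-1.66, chosen after its values were seen), which had 8.05 in control replicate 3 and 2.36 to 3.59 in the other arrays. Gpx1, the selenoprotein glutathione peroxidase (1.01 ± 0.18), and Gclm, of glutathione synthesis (0.74 ± 0.17), were the 2 of 25 members that rose adjusted over the list alone, with 0 over all genes. Hmox1, heme oxygenase, differed by 0.85 ± 0.29 and did not pass (adjusted p = 0.513; without sickle replicate 3 the difference was 0.54 and the adjusted p 0.531). Interferon response genes did not pass as a list (median -0.07, mean 0.11, camera adjusted p = 0.629), and Rsad2 and Isg15 (1.13 ± 0.24) were the 2 of 16 members that rose adjusted over the list alone, with 1, Rsad2, over all genes.

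Around the beta-globin locus, where the groups carry different engineered alleles, few genes could be called, since 121 of 148 measured neighbours are olfactory receptor genes and 12 are brighter than the median gene. Of these 148 neighbours, 0 (0%) were called by limma, against 0.183% of the other genes (two-sided Fisher's exact test, p = 1). Among the 500 genes with the smallest p, 6 were neighbours (4.05%, against 2.31% elsewhere; two-sided Fisher's exact test, p = 0.162).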

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

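The tests of array scaling, of array quality and of a wrong label for sickle replicate 3, and those of calls by chromosome, were chosen only after the result was seen. Outside the 21506 tested genes, 4 further rows differed between the groups when all rows were fitted with limma, all of them higher in the sickle arrays and in 3 of 3 of these above every control array. A row without a symbol (ID 17502789) rose by 3.51 ± 0.22 (SE; adjusted p = 0.00212), and another (ID 17467250) by 2.53 ± 0.20 (adjusted p = 0.00536). Another 2 rows that the annotation gives to several genes rose by 2.82 ± 0.18 and 1.56 ± 0.20 (limma adjusted p = 0.00212 and 0.0479). The former is given to Apex2 and to Alas2, of the red-cell list, and its rise cannot be assigned to either. No gene is named from the latter.

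With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 39 called genes, as many as 1 of the 10 splits (itself), and the highest other gave 1. At the looser limit the real split gave 178 genes, again matched by 1 of 10 (itself), and the highest other 59. For gene lists at the preset correlation, 4 of the 10 splits gave at least the real 14, and the highest other gave 16. Counting the real one, the matrix and fibroblast lists passed in 10 of the 10 splits, the macrophage list in 9, oxidative phosphorylation in 8, the red-cell list in 7, fatty acid oxidation in 6, cell cycle in 4 and lymphocyte markers in 3. For cell cycle genes another split gave a smaller unadjusted p (1.66e-12) than the real one (5.08e-10), while for the red-cell list the real p was 7.96e-28 and the smallest other 6.67e-06.

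The first pattern is the rise of red-cell transcripts in the sickle ventricle, a list with 9 of 18 measured members brighter than the median gene in control and none shared with another list. More whole blood of unchanged makeup in the sickle samples would raise white-cell markers as much as red-cell markers, and among members brighter than the median gene the red-cell median exceeded the white-cell one by 1.60 (95% bootstrap interval over genes 0.18 to 1.89). An interval above 0 had been set as evidence against that explanation, but the white-cell side came to hold 1 gene, Csf3r (0.11), since the abundant neutrophil genes S100a8 and S100a9 lay near the floor (3.28 and 3.67 in control), so the test is too thin to decide. Cd79a (1.12) was also higher, which goes with added blood, while the lymphocyte and neutrophil medians of 0.26 and 0.11, over mostly dim genes, lay below the red-cell median of 1.55. Added blood therefore cannot be told apart from more immature red cells per volume of blood, a difference that the sickle genotype itself may bring and that was not tested.

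The second pattern is the high matrix, fibroblast and macrophage expression in sickle replicate 3. For scaling of the whole array, the matrix list's median was 1.97 above the mean of the other sickle arrays. The highest of 10000 random lists matched on mean expression reached 0.25. Quantile normalisation holds random lists near 0, and the matrix list was chosen as high in this array, so this is no independent test. The values show only that no shift of that size was common to genes of like brightness. Atrial tissue in the sample is argued against by Myl7, Myl4, Sln and Bmp10, whose median deviation was -0.088 while the matrix list's lower quartile was 1.35, and a control mouse labelled sickle by the red-cell median of 1.58 in this array, where the control arrays reached at most 0.03. A quality fault that moves correlated genes together cannot be told apart from a true difference, since the array's low weight of 0.358 and its correlations with its group mates of 0.985 and 0.984, against 0.993 between those, would follow from either. A difference of this 1 mouse from its group mates, or connective tissue taken along in dissection, may remain as explanations, and no biological explanation was tested since the labels give the mouse no group of its own.

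The third pattern is the set of called genes outside the red-cell list, above all the lower ones (Timp4, Scn4b and Car4). Of the 36 genes called higher, 25 were on no list. They included the globin genes Hbq1a and Hba-x and the carbonic anhydrase gene Car2. The first pattern may therefore reach beyond its list, and how many of the 25 belong to it was not tested. Dilution of heart RNA by added red-cell RNA would lower all heart transcripts alike. The sarcomere list's median was -0.053 ± 0.025 (bootstrap SE; 0.04 without sickle replicate 3), well above the -0.90 to -1.57 of the genes called lower. This cannot decide on dilution, since quantile normalisation takes out a fall shared by most genes. The genes called lower were also picked for their low values. The values show only that these genes fell further than the sarcomere genes. For a linked strain haplotype around the beta-globin locus, a count of called neighbours below 5 had been set as evidence against it as the source of an eighth of the calls, but the 0 (0%) found decides nothing: 121 of the 148 neighbours are olfactory receptor genes, 12 are brighter than the median gene, and 0.125 calls were expected at that brightness. A haplotype linked to that locus anywhere on chromosome 7, as the source of an eighth or more of the calls, would still need 5 called genes on chromosome 7, which held 3 of the 39 (3.46 expected). Chromosome 11 held 8 calls where 2.96 were expected (two-sided Fisher's exact test, p = 0.00798, adjusted p = 0.168 over 21 chromosomes). These 8 included Slc4a1, of the red-cell list, and the globin genes Hbq1a and Hba-x, so part of that count belongs to the first pattern. Smaller contributions of linkage, haplotypes on other chromosomes and an effect of the sickle genotype on heart muscle stay open and may all contribute.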

How the results depend on the processing

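All alternatives were planned before the data were examined. Of 1420 values for named genes under them, 1308 kept their side of the threshold, 91 lost a call and 21 gained one. Most named genes were not called over 6 arrays and so had no call to lose. Without control replicate 3 alone, 19 named genes lost theirs. For 433 gene list medians the numbers were 370, 49 and 13, and 1 further list median turned its sign as the list lost its call. The sign turned in 18 and 31 of these values, such as Il18 without sickle replicate 3, and 1 of the turned values, the median of the coagulation and complement list, belonged to a call: it was 0.26 over 6 arrays and ranged from -0.012 without sickle replicate 3, where the list was not called, to 0.38 without sickle replicate 1. The 39 called genes became 12 with the replicate number as a block, 0 by a test of each gene with its own variance alone (1740 genes at an unadjusted p under 0.05), where 4 residual degrees of freedom and no shared variance limit it, and 4 to 36 when an array was left out, which leaves fewer samples. The 178 genes at the looser limit became 108 among genes brighter than the median, where fewer genes are tested, 77 by the test without shared variance, and 153 to 278 with an array left out, the highest without sickle replicate 2. The 14 lists became 9 with array weights (weight 0.36 for sickle replicate 3, 1.05 to 1.39 for the others), 0 with an estimated correlation, 1 by fry and 7 to 16 with an array left out; apart from the left-out arrays the cause was not tested. The other settings gave 32 to 50 called genes, 32 with arrays centred on their medians, 44 after a second quantile normalisation, and 50 with array weights or another variance model. Deviations of same-numbered arrays from their group means had correlations across genes of 0.11, -0.05 and 0.05 for replicates 1, 2 and 3. The 0.11 was the highest of all pairs of a control and a sickle array. Sickle replicates 2 and 3 correlated best with control replicates 1 (0.06) and 2 (0.07). These values gave no clear sign of pairing, but 3 arrays per group cannot exclude it, so the block is given beside the main fit. The glucocorticoid list, not called over 6 arrays, was called without sickle replicate 3. No measure of signal over background was used here, so whether dim genes such as Il18 (18.0 percentile) lay above background was not tested.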

Other observations

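The circadian clock list did not pass as a whole, with 10 of its 17 measured genes higher and 7 lower in sickle. Of these, 4 rose adjusted over the list alone and 0 over all genes: Per3 by 0.70 ± 0.16, Ciart by 0.60 ± 0.18, Dbp by 0.44 ± 0.12 and Tef by 0.41 ± 0.12 (list median 0.12, camera adjusted p = 0.0788). The glucocorticoid response list had a median of -0.01 and a mean of -0.20 (camera adjusted p = 0.286), with Pdk4 the 1 of 13 members that fell adjusted over the list alone (0 over all genes). Relative to control, its median was -0.43 and -0.08 in sickle replicates 1 and 2 and 0.44 in replicate 3. Without replicate 3 the list's median was -0.38 and camera called it lower (adjusted p = 8.24e-05, and adjusted p = 0.798 with an estimated correlation).

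Adipocyte markers had a median of -0.15 (camera adjusted p = 0.0849). Their median relative to control was 0.05, -0.18 and -0.17 in sickle replicates 1, 2 and 3. Cidea, a lipid droplet protein, was the 1 of 12 that fell adjusted over the list alone (-0.54 ± 0.11, with 0 over all genes). Heat shock genes (median -0.12, camera adjusted p = 0.101) and unfolded protein response genes (median -0.07, camera adjusted p = 0.212) did not pass. In these lists Hsp90aa1 differed by 0.74 ± 0.18, Hspe1 by -0.49 ± 0.19, Hspb1 by -0.27 ± 0.13, Sdf2l1 by -0.42 ± 0.18, Asns by 0.39 ± 0.14 and Manf by -0.33 ± 0.10, with 0 members past either adjustment.

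The genes that set sickle replicate 3 apart from its group mates were chosen after their values were seen. Lox, which crosslinks collagen, was 4.36 above the mean of the other sickle arrays on the log2 scale, Sprr1a, a gene induced in stressed cardiomyocytes and neurons, 4.28, Col12a1 3.60, Cilp 3.50 and Tnc (tenascin C) 3.00. Postn had 12.40 in this array, against 9.28 and 9.64 in the other sickle arrays and a control mean of 8.59. In the matrix list, 20 of 24 genes were over 2-fold above the mean of the other sickle arrays. These are values of 1 mouse, and no test across groups bears on them.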
